A study of Homo sapiens with 36 samples.

How the data were processed

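The deposited values were intensities: per the labels, signals from 36 Illumina Human-6 version 2 arrays, 12 for each of the lines HES2, MEL1 and H9, with 3 replicates of each of 4 sorted fractions. Per the labels, RNA had been extracted with a column kit, checked on a Bioanalyzer, amplified with the Illumina TotalPrep kit and detected with Cy3. The intensity table made by the authors held 48687 probes on a linear scale. Its sorted values were the same for the 12 arrays of a line to within 0.0472 log2 and differed between lines, which is the mark of quantile normalisation within each line by the authors. Every value was above 0, from 4.43 to 45648 in HES2, from 4.10 to 64751 in MEL1 and from 2.19 to 61492 in H9, and genes had not been centred; the values do not show whether background had been removed. The processing notes of the submitters name BeadStudio and RMA; which step each was used for is not given in the sources used here. Quantile normalisation within a line removes any difference in total RNA between fractions, so every change is relative to the other genes of that line, and intensities were not compared directly between lines.

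Per the file headers, the 3 deposited scanner tables came from BeadStudio 2.3.41 without normalisation. Their 36 columns of array signals are named by chip and position, which no label ties to a sample, so they were left out, and neither detection p-values nor the chip of an array could be used. The plan made before the data were examined set the value table on a log2 scale as the fallback for this case; that plan also fixed the groups, comparisons, tests, gene lists and most alternatives. The plan's filter on detection p-values was replaced by an intensity floor, chosen after seeing the data: the 70th percentile of all values of a line, 27.4 in HES2, 70.4 in MEL1 and 42.8 in H9. A probe was kept in a line when all 3 arrays of at least 1 fraction exceeded the floor.

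Gene symbols came from the platform annotation and were checked through their gene identifiers against the RefSeq gene table of GRCh38. Of the probes, 23675 had 1 symbol, 35 several and 24977 none; 0 symbols needed an update and 36 identifiers had no match. The remaining 18773 genes were each represented by the probe with the highest mean intensity over the arrays used, and 10980 (58.5%) were tested in HES2, 11338 (60.4%) in MEL1 and 11127 (59.3%) in H9. Genomic positions are not given, since the gene table used holds none. Other probes of a named gene were compared with the one used. For MEST a second probe gave -4.43, -3.48 and -3.74 log2 between p7 and p4 in HES2, MEL1 and H9, against 0.32, 0.79 and 0.93 for the brightest, and HK1, PRDM1 and TGIF1 also had probes of opposite sign, so no values of these genes are given elsewhere except where a setting turned one. Second probes with the same sign whose log2 difference between p7 and p4 lay over 1 from the one used gave, among genes in the text, -8.55 and -8.08 for DLK1 in HES2 and MEL1, -4.06 and -5.10 for OTX2 in HES2 and MEL1, 2.46 and 2.90 for EDNRB in MEL1 and H9, 5.06 and 2.10 for 2 probes of POU5F1 in MEL1 and 0.76 for 1 in H9, -3.67 for HOPX in H9 and -3.91 for PRRX1 in H9.

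Fits were made in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend), 1 mean per fraction and all 12 arrays of a line in the fit. Contrasts were p7 minus p4 and the neighbouring steps p5 minus p4, p6 minus p5 and p7 minus p6. A joint fit of all 36 arrays with 12 group means gave the average of p7 minus p4 over lines and its difference between pairs of lines. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were counted. Tests were two-sided, except that a gene was called highest in a fraction by the largest of its one-sided p-values against the other fractions. For a gene whose mean in the lower fraction lay below the floor, values of that fraction below the floor were set to it, and the fold was given as a lower bound. Replicates were not paired in the tests, as the labels do not say that their numbers pair across fractions. In MEL1 and H9, though, residuals of arrays with the same number correlated over 0.1 in all 3 pairs of each neighbouring step (lowest 0.234, 0.313 and 0.276 in MEL1 and 0.142, 0.237 and 0.567 in H9 for p4 with p5, p5 with p6 and p6 with p7), of p5 with p7 (0.209 and 0.180) and, in MEL1, of p4 with p6 (0.124), so the numbers were taken to pair these fractions, from the data and not from the labels. Not every pair was over 0.1 for p4 with p7 in any line (lowest 0.0986 in MEL1 and -0.093 in H9). The same held for p4 with p6 in H9 and for every combination of fractions in HES2. Numbers that pair p4 with p5 and p5 with p7 also pair p4 with p7, so in MEL1 and H9 these low values leave that pairing standing. In HES2 pairing stays open. The main tests were unpaired throughout, and a replicate block was run as an alternative.

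The 25 gene lists named in the report were written before the data were examined, with 606 members, of which 553 had a probe; some genes are in several lists. Each was tested with camera at a preset correlation of 0.01, adjusted over lists and lines, and again with an estimated correlation. Of 75 combinations of list and line, 47 passed between p7 and p4, and 19 with an estimated correlation. Members were counted over all genes tested and with p-values adjusted over the list alone. The named genes followed a rule fixed with the plan: CD9; the 12 largest rises and 12 largest falls common to the 3 lines; per line the 10 largest of each; per list and line up to 2 of each; per neighbouring step and line 3 of each; and per pair of lines 5 of each sign. Rises and falls had to pass the test, and those within a line had to show no overlap between the 3 arrays of each fraction. Left out were probes without a proper gene name and XIST and Y-linked genes. Genes named outside this rule are marked where they appear.

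Alternatives were all 36 arrays normalised together, no filter, a filter that asks every array to exceed the floor, the mean of a gene's probes, a replicate block, array weights, only the fractions compared in the fit, a required log2 difference over 1, and each array left out in turn. Added after seeing the data were an offset of 16 before the log, values floored, filters at the 60th and 80th percentile, the list differences between lines without H9 p4 replicate 2, with values floored and over genes tested in both lines, and the lists of neighbouring steps with a replicate block. On simulated data built from the arrays, with 50 changed genes per size, log2 changes of 0.5, 1, 2 and 4 were recovered for 6%, 48%, 86% and 100% of genes in HES2, 38%, 84%, 100% and 100% in MEL1 and 16%, 72%, 96% and 98% in H9, with 4, 10 and 4 false calls. Few genes changed in the simulation, while 46.0%, 66.9% and 48.5% of genes passed between p7 and p4 in HES2, MEL1 and H9. The adjusted threshold is looser where many genes change, so the recovered shares describe a comparison with few changes. For arrays, the number of replicates limits the precision.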

Results

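Gene expression was measured on 36 Illumina Human-6 version 2 bead arrays of 3 human embryonic stem cell lines. HES2 and MEL1 had been grown in medium with knockout serum replacement (KOSR), and H9 in mTeSR, a defined medium. Each culture had been sorted by flow cytometry for GCTM-2, an antibody against a cell surface proteoglycan of pluripotent cells, and for the tetraspanin CD9, into 4 fractions named p4, p5, p6 and p7. The labels do not state how brightly each fraction stained; in published work with this sort, p4 holds the unstained cells and p7 the brightest. The 12 groups of line and fraction held 3 arrays each, which per the series design text came from consecutive passages. The p-values therefore measure the spread between these samples, which may be technical in part, and the number of arrays limits the precision of every value. The median intensity of an array was 13.3 in HES2, 15.5 in MEL1 and 11.8 in H9, and 10980, 11338 and 11127 genes were bright enough to test. Correlations between replicates, across genes that are not independent of each other, ran from 0.956 to 0.987 in HES2, from 0.986 to 0.994 in MEL1 and from 0.962 to 0.990 in H9. H9 p4 replicate 2 stood apart from its group: it correlated with the p5 mean at 0.974 and with the mean of the other arrays of its group at 0.971. In that array CD9 stood at 12.86 (log2 intensity), against 11.05 and 10.66 in the other p4 arrays. The p6 and p7 arrays of H9, and p6 replicate 3 and p7 replicate 3 of HES2, also lay nearer the mean of the other of these fractions. A group mean without the array itself holds fewer arrays, which by itself lowers its correlation a little. HES2 p5 replicate 2 correlated with the other arrays of its group at 0.960 and 0.956, the lowest values in HES2. Levels below are mean log2 intensities ± SD (n = 3 arrays), and differences carry their SE from limma.

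The first comparison asked which genes differed between the fractions at the ends of the sort, p7 and p4. CD9, an antigen of the sort itself, rose from 9.45 ± 0.41 in p4 to 13.14 ± 0.20 in p7 of HES2, a 12.9-fold difference (3.69 ± 0.19 log2, adjusted p = 2.7e-09). In MEL1 it rose 19.2-fold, from 10.34 ± 0.45 to 14.61 ± 0.03 (adjusted p = 1.72e-11), and in H9 6.32-fold, from 11.53 ± 1.18 to 14.19 ± 0.25 (adjusted p = 0.000106). CHST4, a sulfotransferase that acts on carbohydrate chains, was among the 12 largest rises common to the lines. It was at least 40.0-fold higher in p7 of HES2, at least 31.6-fold higher in MEL1 and 10.3-fold higher in H9 (3.37 ± 0.34 log2). "At least" marks a gene whose mean in the lower fraction lay below the intensity floor; for its fold, values there below the floor were set to it. TRIML2 rose 31.0-fold in HES2, at least 35.3-fold in MEL1 and 8.96-fold in H9. The long noncoding RNA LNCPRESS1 rose 42.7-fold, at least 41.1-fold and 5.02-fold in the same order, and IDO1, which degrades tryptophan, 27.9-fold, 26.8-fold and 6.33-fold. PMAIP1, a proapoptotic BCL2 family member, rose at least 11.5-fold in HES2, 21.8-fold in MEL1 and 4.19-fold in H9. Without p4 replicate 2 the H9 folds were 10.1 for CD9, 20.2 for TRIML2, 9.85 for LNCPRESS1, 11.9 for IDO1 and 6.61 for PMAIP1; TRIML2 was 5.22-fold higher there without p4 replicate 1, LNCPRESS1 2.70-fold and IDO1 3.91-fold without p4 replicate 3, and LNCPRESS1 in HES2 at least 69.4-fold without p4 replicate 1.

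LHX2, a LIM homeobox factor of the developing forebrain and eye, fell at least 208-fold in HES2, from 12.71 ± 0.13 to 4.22 ± 1.15 (adjusted p = 5.55e-09), at least 101-fold in MEL1 and at least 34.2-fold in H9. TYRP1, an enzyme of melanin synthesis, fell at least 198-fold, at least 119-fold and at least 8.19-fold in HES2, MEL1 and H9. DLK1, an imprinted Notch ligand homologue, fell 140-fold in HES2 (15.10 ± 0.14 to 7.97 ± 0.45), 96.7-fold in MEL1 (15.61 ± 0.07 to 9.02 ± 0.22) and 45.4-fold in H9 (14.30 ± 0.24 to 8.79 ± 1.2), with adjusted p of 3.07e-11, 7.95e-12 and 3.13e-06. The Wnt antagonist DKK1 fell 39.1-fold, 16.1-fold and 156-fold, and LEF1, a transcriptional mediator of Wnt signals, 25.1-fold, 22.2-fold and 28.0-fold. Leaving out H9 p7 replicate 1 gave a fall of 28.3-fold for DLK1 and 80.1-fold for DKK1 in H9. In HES2, 2693 genes were higher and 2360 lower in p7 than in p4. The counts were 3973 and 3612 in MEL1, and 3110 and 2291 in H9. With a log2 difference over 1 also required, 2936 genes in HES2, 2832 in MEL1 and 2463 in H9 passed. Over all genes tested the median shift was 0.07 log2 in HES2, 0.03 in MEL1 and 0.13 in H9.

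**Figure D1:**
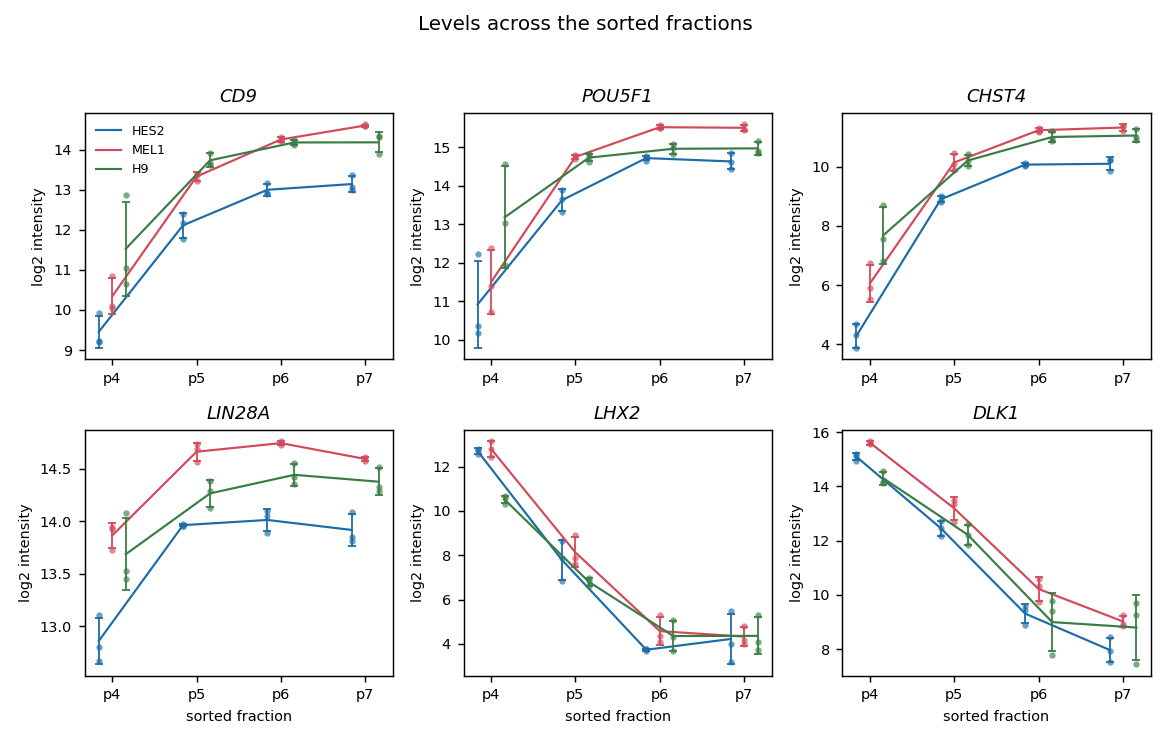
Log2 intensity of CD9, POU5F1, CHST4, LIN28A, LHX2 and DLK1 in the sorted fractions p4 to p7; points are single arrays, lines join the means, bars are the SD (n = 3) and colour marks the line. CD9, POU5F1, CHST4 and LIN28A were higher and LHX2 and DLK1 lower in p7 than in p4 of each line, with the widest p4 spread of CD9 in H9 (SD 1.18).

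Genes of the pluripotency list were higher in p7. Of its members tested, 22 of 27 rose and 1 fell in HES2, 24 of 28 rose and 1 fell in MEL1, and 23 of 26 rose with 0 falls in H9. Adjusted over the list alone, the counts were 22 and 1, 24 and 2, and 24 and 1. Camera gave adjusted p = 5.2e-11 in HES2, 3.33e-09 in MEL1 and 8.27e-07 in H9; adjusted p = 0.0401, 0.0714 and 0.252 with an estimated correlation. POU5F1, the pluripotency factor OCT4 (chosen after its values were seen), rose 13.1-fold in HES2 (3.71 ± 0.36 log2, adjusted p = 1.01e-06), 16.1-fold in MEL1 (4.01 ± 0.26, adjusted p = 4.64e-09) and 3.46-fold in H9 (1.79 ± 0.43, adjusted p = 0.00375). NANOG, another core factor, rose 45.8-fold in MEL1 and 6.43-fold in H9. Its single probe lay below the floor on all 12 arrays of HES2 and was not tested there. SOX2, also on the list, was too dim to test in MEL1 and H9 and was not among the members that rose in HES2. Likewise too dim to test were FGF4 in HES2 and H9 and KLF4 in H9. UTF1, a chromatin protein of undifferentiated cells, rose at least 13.8-fold in HES2, at least 9.02-fold in MEL1 and at least 5.38-fold in H9. The TGF-beta family member GDF3 rose at least 21.2-fold, 10.7-fold and 2.35-fold. OTX2, a homeobox factor also expressed in forebrain and eye, moved the other way: it fell by 1.02 log2 in HES2 and by 1.37 in MEL1 (by 4.06 and 5.10 with a second probe), and its difference in H9 was 0.38 log2 (adjusted p = 0.0818). In H9 p4, POU5F1 stood at 14.57 on replicate 2 and at 13.02 and 11.93 on replicates 1 and 3. The H9 folds were 5.61 for POU5F1 and 12.2 for NANOG without p4 replicate 2 and 2.25 and 3.77 without p4 replicate 3, and POU5F1 rose 20.6-fold in HES2 without p4 replicate 1.

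Stem cell surface genes, a list that includes CD9 itself, were also higher in p7. In HES2 19 of 23 rose and 0 fell, in MEL1 15 of 23 rose and 0 fell, and in H9 18 of 23 rose and 1 fell; adjusted over the list alone, 19 and 0, 15 and 0, and 19 and 1. Camera gave adjusted p = 2.95e-08, 1.48e-05 and 1.49e-06, and adjusted p = 0.0562, 0.0286 and 0.0401 with an estimated correlation. CNMD (chondromodulin) rose 39.3-fold in HES2, 19.8-fold in MEL1 and 7.08-fold in H9 (11.4-fold without p4 replicate 2), and the adhesion receptor ADGRG2 11.9-fold, 5.42-fold and 9.05-fold. THY1, the surface antigen CD90, rose 3.16-fold, 4.32-fold and 1.64-fold.

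Neural genes fell. All 23 tested in HES2 and 21 of 22 in MEL1 fell, with 0 rises. In H9 14 of 19 fell and 3 rose. The counts were the same when adjusted over the list alone. Camera gave adjusted p = 3.45e-17, 2.94e-12 and 3.39e-07, and adjusted p = 0.0286, 0.0401 and 0.0401 with an estimated correlation. PAX6, an eye and forebrain regulator, fell at least 48.1-fold in HES2, at least 43.2-fold in MEL1 and at least 7.51-fold in H9. The Notch target HES5 fell 195-fold, at least 53.7-fold and at least 45.9-fold. SOX3, a factor of neural progenitors, fell 6.12-fold in HES2 and 2.73-fold in MEL1 and rose 2.0-fold in H9 (adjusted p = 0.000688). Of the neural crest list, 8 of 11 fell and 1 rose in HES2, 10 of 12 fell and 2 rose in MEL1, and 7 of 9 fell and 2 rose in H9, with the same counts adjusted over the list alone. Its camera adjusted p was 0.00508, 0.000405 and 0.000556; adjusted p = 0.196, 0.134 and 0.217 with an estimated correlation, 0.0792, 0.0522 and 0.197 by camera with every array above the floor, and 0.0935 in HES2 with the filter at the 80th percentile. TFAP2B, a neural crest factor, fell at least 4.41-fold in HES2 and at least 19-fold in MEL1. EDNRB, the endothelin receptor of migrating crest cells, rose 2.66-fold in MEL1 and 2.37-fold in H9 (by 2.46 and 2.90 log2 with a second probe).

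Mesoderm, endoderm and stromal genes were lower in p7 as well. Of the primitive streak and mesoderm list, 11 of 15 fell and 1 rose in HES2, 13 of 19 fell and 2 rose in MEL1, and 16 of 18 fell and 0 rose in H9 (adjusted over the list alone, 11 and 1, 14 and 2, and 16 and 0). Camera adjusted p was 4.47e-05, 0.00189 and 2.94e-12; adjusted p = 0.0401, 0.279 and 0.0883 with an estimated correlation. HAND1, a factor of lateral mesoderm and trophoblast, fell 13.6-fold, 4.81-fold and 46.7-fold, and the apelin receptor APLNR 30.1-fold, 7.06-fold and 79.1-fold in HES2, MEL1 and H9. Without p7 replicate 1 the falls were 24.8-fold for HAND1 and 43.2-fold for APLNR in H9 and 4.40-fold for APLNR in MEL1, and HAND1 fell 70.6-fold in H9 without p7 replicate 2. Of the endoderm list, 17 of 22 fell in HES2 and 20 of 23 in MEL1, with 1 rise in each, and 18 of 20 fell in H9 with 0 rises; adjusting over the list alone gave the same counts. The list test gave adjusted p = 9.54e-09, 4.76e-05 and 5.92e-11; adjusted p = 0.0401, 0.31 and 0.0823 with an estimated correlation. The chemokine receptor CXCR4 fell 13.3-fold, 8.41-fold and 10-fold, and the pioneer factor FOXA2 5.24-fold, 2.90-fold and at least 32.1-fold.

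Fibroblast and stroma genes fell in 20 of 26 cases in HES2, 20 of 26 in MEL1 and 25 of 26 in H9, with 1 rise in each line (adjusted over the list alone, 20, 21 and 25 falls). By camera, the adjusted p was 5.82e-08, 9.33e-07 and 9.66e-17; adjusted p = 0.0373, 0.217 and 0.0433 with an estimated correlation. The collagen gene COL3A1 fell at least 36.9-fold in HES2, 22.3-fold in MEL1 and 57.8-fold in H9 (22.8-fold, 93.9-fold and 90.2-fold without p7 replicates 1, 2 and 3), and the mesenchymal homeobox gene PRRX1 at least 7.18-fold, at least 10.7-fold and at least 68.6-fold. Of the mesenchymal transition list, 8 of 12 fell in HES2, 12 of 17 in MEL1 and 15 of 16 in H9, with 0, 1 and 0 rises; adjusted over the list alone, falls numbered 9, 12 and 15 and rises 0, 1 and 1. For this list camera returned adjusted p = 0.000165, 0.000278 and 2.93e-11; adjusted p = 0.0373, 0.181 and 0.0401 with an estimated correlation. ZEB2, a repressor of E-cadherin, fell at least 31.0-fold, at least 35.6-fold and at least 25.8-fold. Of the smooth muscle and actin list, 8 of 17 fell in HES2, 7 of 16 in MEL1 and 9 of 16 in H9, with 1, 3 and 1 rises (adjusted over the list alone, falls 8, 6 and 9, rises 1, 3 and 2). Tested with camera, its adjusted p was 0.00934, 0.228 and 0.000319, and adjusted p = 0.0681 in HES2 and 0.118 in H9 with an estimated correlation. The actin gene ACTA2 fell 30.1-fold, 14.7-fold and 14.5-fold.

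HOX cluster genes, which set position along the body axis, fell in 7 of 8 cases in HES2, 10 of 11 in MEL1 and 17 of 18 in H9, with 0 rises and the same counts adjusted over the list alone. Camera adjusted p was 5.82e-05, 0.000319 and 1.84e-13; adjusted p = 0.0401, 0.252 and 0.0407 with an estimated correlation. HOXB2 fell at least 32.5-fold in HES2, 11.2-fold in MEL1 and at least 41.3-fold in H9, and HOXC6 at least 3.33-fold, at least 6.28-fold (at least 11.1-fold without p4 replicate 1) and 150-fold (73.4-fold without p7 replicate 1). Of the BMP signalling list, 11 of 14 fell in HES2, 13 of 15 in MEL1 and 12 of 14 in H9, with 1, 1 and 0 rises (adjusted over the list alone, falls 12, 13 and 13). The list test gave adjusted p = 2.45e-06, 1.59e-05 and 7.55e-09; adjusted p = 0.0286, 0.0286 and 0.104 with an estimated correlation. The BMP target MSX1 fell 24.5-fold, 15.3-fold and 62.7-fold (40.2-fold without p7 replicate 1). Of the WNT signalling list, 14 of 20 fell in HES2, 15 of 20 in MEL1 and 16 of 21 in H9, with 3, 2 and 4 rises and the same counts adjusted over the list alone. By camera, the adjusted p was 4.5e-06, 5.32e-05 and 1.78e-05; adjusted p = 0.0286, 0.0681 and 0.125 with an estimated correlation. RSPO3, which amplifies Wnt signals, fell 99.4-fold, 6.09-fold and at least 88.3-fold.

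The NODAL and TGF-beta list split its members. In HES2 6 of 15 rose and 3 fell, in MEL1 6 of 15 rose and 4 fell, and in H9 2 of 14 rose and 7 fell (adjusted over the list alone, 6 and 4, 7 and 4, and 2 and 7). For this list camera returned adjusted p = 0.818 in HES2 and 0.36 in MEL1, and 0.00393 for a fall in H9; adjusted p = 0.253 there with an estimated correlation. LEFTY1, a secreted NODAL antagonist, rose 16.9-fold in HES2 (37-fold without p4 replicate 1, 7.93-fold without p4 replicate 3) and 18.8-fold in MEL1, and its difference in H9 was 0.74 ± 0.37 log2 (adjusted p = 0.112). LEFTY2, its paralogue, rose 2.28-fold in MEL1, fell 34.0-fold in H9 and differed by 0.03 ± 0.46 log2 in HES2 (adjusted p = 0.959). SMAD3, a transducer of TGF-beta signals, fell 5.10-fold, 3.05-fold and 3.03-fold.

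Among the extraembryonic and blood lists, trophoblast genes fell in 3 of 8 cases in HES2, 6 of 7 in MEL1 and 6 of 8 in H9, with 1, 1 and 2 rises (adjusted over the list alone, falls 4, 6 and 6). Tested with camera, its adjusted p was 0.0307, 0.0242 and 0.00176; adjusted p = 0.226, 0.217 and 0.162 with an estimated correlation. The HES2 call was lost, with camera adjusted p from 0.0533 to 0.118, with no filter, with every array above the floor, with values floored, with filters at the 60th and 80th percentile, without p4 replicate 3 (0.0540), without p5 replicate 2 (0.0550) and with only p4 and p7 in the fit. The MEL1 call was lost with no filter (0.0818), with filters at the 60th and 80th percentile (0.0741 and 0.252) and with every array above the floor (0.630). PAPPA, a placental metalloprotease that stromal cells also make, fell 16.1-fold, 18.3-fold and 11.9-fold (7.62-fold without p7 replicate 1), while TFAP2C, a factor of trophoblast and germ cells, rose 2.65-fold, 2.65-fold and 4.57-fold. Endothelial and blood genes fell in 6 of 9 cases in HES2, 6 of 10 in MEL1 and 7 of 8 in H9, with 2, 3 and 1 rises (adjusted over the list alone, falls 6, 6 and 7, rises 2, 4 and 1). Camera adjusted p was 0.0269, 0.103 and 0.000189, and adjusted p = 0.226 in HES2 and 0.0724 in H9 with an estimated correlation. With no filter and with the filter at the 60th percentile HES2 was no longer past the threshold (0.0577 and 0.0971) and MEL1 came past it (0.0148 and 0.0437), as it did at the 80th percentile (0.00399). The fetal globin gene HBG1 fell at least 25-fold in HES2 (at least 15.8-fold without p4 replicate 2) and at least 55.7-fold in MEL1. The receptor gene FLT1 rose at least 2.03-fold, at least 2.06-fold and 1.74-fold. Imprinted growth genes fell in 7 of 11 cases in HES2, 8 of 12 in MEL1 and 8 of 13 in H9, with 1, 4 and 3 rises (adjusted over the list alone, falls 8, 8 and 8). The list test gave adjusted p = 0.000319, 0.0184 and 0.00108; adjusted p = 0.0373, 0.0808 and 0.0461 with an estimated correlation, and 0.0983 in MEL1 by camera with every array above the floor. PLAGL1, an imprinted zinc finger gene, fell at least 19.6-fold, at least 12.6-fold and at least 8.93-fold, and SNRPN, a splicing protein gene, rose 2.49-fold, 2.54-fold and 1.79-fold.

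**Figure D2:**
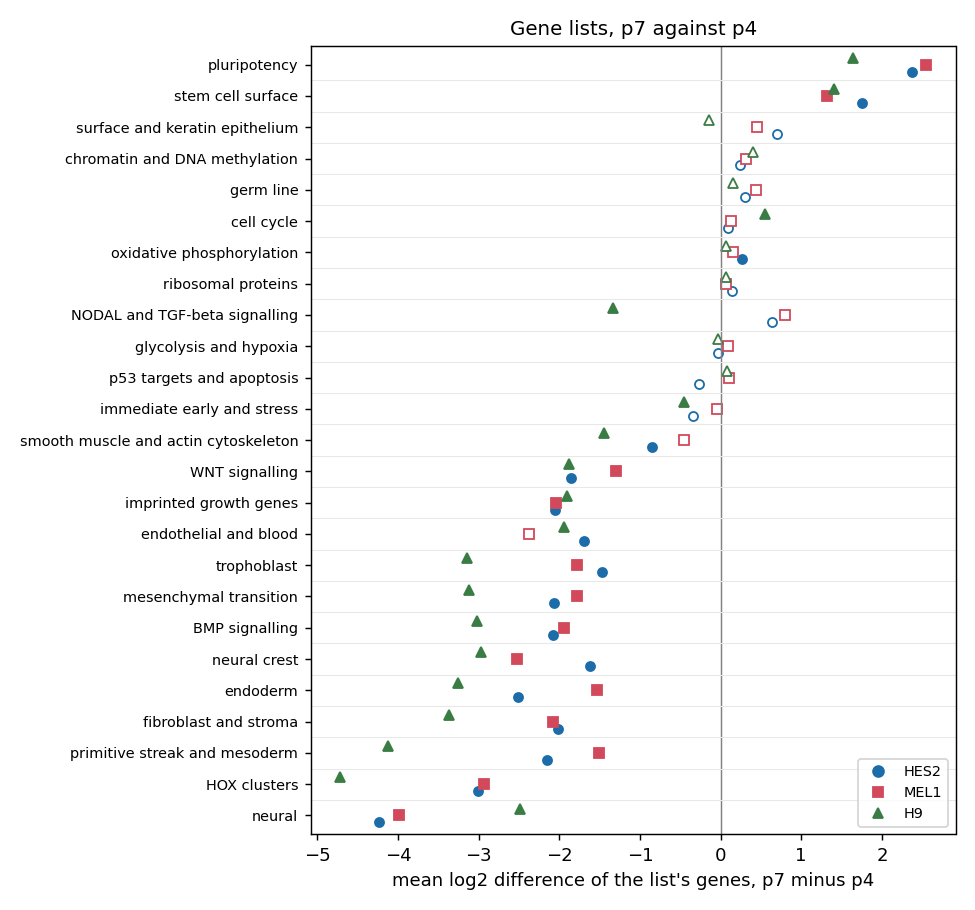
Mean log2 difference between p7 and p4 over the tested genes of each of the 25 lists, by line; filled symbols passed camera at an adjusted p of 0.05 and open ones did not. The pluripotency list lay at 2.37, 2.55 and 1.64 in HES2, MEL1 and H9 and the neural list at -4.23, -3.99 and -2.48.

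Cell cycle genes moved with the sort in H9: 23 of 35 rose and 1 fell (26 and 1 adjusted over the list alone; camera adjusted p = 0.000142; adjusted p = 0.253 with an estimated correlation). In HES2 9 rose and 4 fell and in MEL1 12 rose and 10 fell of 35 (adjusted over the list alone, 8 and 4, and 12 and 10), with camera adjusted p of 0.914 and 0.663. The replication licensing gene CDC6 rose 2.6-fold, 2.52-fold and 2.26-fold. CENPF, a kinetochore protein gene, fell 2.46-fold in HES2 and 1.90-fold in MEL1 and rose 1.79-fold in H9. Oxidative phosphorylation genes rose in 7 of 23 cases in HES2 with 0 falls (camera adjusted p = 0.0429; adjusted p = 0.261 with an estimated correlation; 0.0578, 0.0563 and 0.0785 by camera without p4 replicate 1, p4 replicate 2 or p7 replicate 3, and 0.0631 with every array above the floor). In MEL1 10 of 23 rose and 1 fell and in H9 1 rose and 1 fell (camera adjusted p = 0.181 and 0.87); adjusted over the list alone, the rises were 7, 8 and 1 and the falls 0, 1 and 1. SDHD, a subunit of succinate dehydrogenase, rose 2.01-fold in HES2 and 1.74-fold in MEL1.

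Immediate early and stress genes fell in 3 of 19 cases in HES2, 8 of 18 in MEL1 and 10 of 18 in H9, with 2, 5 and 1 rises (adjusted over the list alone, falls 3, 8 and 10, rises 2, 5 and 2). By camera, the adjusted p was 0.444, 0.85 and 0.0242, and adjusted p = 0.139 in H9 with an estimated correlation. DUSP6, a phosphatase induced by FGF and ERK signals, fell at least 7.63-fold, 5.63-fold and 3.34-fold, and ASNS, an amino acid response gene, rose 2.65-fold, 3.34-fold and 2.13-fold. MYC rose 4.86-fold in HES2 and 4.66-fold in MEL1; its difference in H9 was 0.21 ± 0.15 log2 (adjusted p = 0.256). Of the chromatin and DNA methylation list, 6 rose and 4 fell of 23 in HES2, 9 and 7 of 24 in MEL1 and 9 and 1 of 23 in H9 (adjusted over the list alone, 6 and 5, 9 and 7, and 9 and 1; camera adjusted p = 0.835, 0.732 and 0.104). DNMT3B, a de novo DNA methyltransferase, rose 7.87-fold, 6.48-fold and 3.23-fold (5.10-fold in H9 without p4 replicate 2). The Polycomb genes PHC1 and BMI1 went in opposite directions: PHC1 rose 3.76-fold, 3.83-fold and 3.61-fold, and BMI1 fell 2.59-fold, 2.66-fold and 2.56-fold.

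For the remaining lists camera was not past the threshold in any line, except surface and keratin epithelium in H9 with every array above the floor (adjusted p = 0.000664) and with the filter at the 80th percentile (0.0102), where the mean shift was -1.04 and -0.75 log2. Germ line genes rose in 6 of 10, 6 of 11 and 5 of 10 cases and fell in 3 each (adjusted over the list alone, rises 6, 6 and 6, falls 4, 3 and 4; camera adjusted p = 0.364, 0.197 and 0.548). IFITM1, an interferon-induced membrane protein, rose 6.89-fold, 6.61-fold and 1.92-fold. Surface and keratin epithelium genes rose in 6 of 15, 6 of 15 and 7 of 16 cases and fell in 3, 5 and 7 (adjusted over the list alone, rises 8, 6 and 7, falls 3, 5 and 7; camera adjusted p = 0.201, 0.608 and 0.268). The epithelial splicing regulator ESRP1 rose at least 11.2-fold, 7.87-fold and 5.59-fold, and the phospholipid-binding protein gene ANXA1 fell 5.76-fold, 4.48-fold and 21.6-fold. Of the p53 targets and apoptosis list, 3 of 16, 6 of 17 and 4 of 16 rose and 7, 6 and 2 fell (adjusted over the list alone, rises 4, 6 and 4, falls 7, 6 and 2; camera adjusted p = 0.402, 0.914 and 0.987). GADD45A, a DNA damage response gene, fell 2.59-fold, 2.51-fold and 4.96-fold. Glycolysis and hypoxia genes rose in 5 of 22, 6 of 22 and 4 of 23 cases and fell in 4, 3 and 4 (adjusted over the list alone, rises 4, 6 and 4, falls 4, 3 and 3; camera adjusted p = 0.987, 0.557 and 0.914). NDRG1, a stress-responsive gene, fell 3.59-fold, 2.3-fold and 7.67-fold and ADM, the hypoxia-induced adrenomedullin gene, rose 3.07-fold, 2.18-fold and 4.02-fold. Ribosomal protein genes rose in 2, 4 and 3 of 34 cases and fell in 1, 1 and 0 (adjusted over the list alone, rises 2, 3 and 2, falls 1, 1 and 0; camera adjusted p = 0.548, 0.987 and 0.828). RPS7 rose 2.65-fold, 2.53-fold and 1.74-fold. Mean, median and camera differed in sign for several lists with no call: p53 targets in HES2 (median 0.29, mean -0.27), MEL1 (median 0.04, mean 0.10, camera lower) and H9, cell cycle in HES2 (median -0.04, mean 0.09), glycolysis in HES2 and H9, ribosomal proteins in MEL1 and chromatin in HES2.

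Neighbouring fractions showed where along the sort these differences arose. Between p4 and p5, neural genes fell and pluripotency genes rose in each line: 20 of 23 neural genes fell in HES2, 19 of 22 in MEL1 and 13 of 19 in H9 (adjusted over the list alone, 21, 19 and 14; camera adjusted p = 9.3e-15, 1.8e-10 and 2.12e-07; adjusted p = 0.0296, 0.061 and 0.0548 with an estimated correlation). Of the pluripotency list, 17, 23 and 19 genes rose (adjusted over the list alone, 18, 23 and 21; camera adjusted p = 6.33e-09, 6.59e-09 and 8.78e-07; adjusted p = 0.0841, 0.108 and 0.332 with an estimated correlation). CD9 rose 6.32-fold in HES2, 7.95-fold in MEL1 and 4.63-fold in H9 (7.37-fold without p4 replicate 2). The largest rises included the alkaline phosphatase gene ALPG in HES2 (26.8-fold, adjusted p = 2.14e-09), IDO1 in MEL1 (20.6-fold) and the bile acid transporter gene SLC51A in H9 (at least 3.87-fold). Among the largest falls, HES5 dropped 52.5-fold in HES2 and 40.2-fold in H9, and the eye field gene SIX6 at least 21.3-fold in HES2, at least 12.8-fold in MEL1 and at least 4.60-fold in H9. In all, 1956 genes rose and 1611 fell in HES2, 3415 and 3024 in MEL1, and 1796 and 1368 in H9. The H9 total of 3164 was 1990 without p5 replicate 1, 4536 without p4 replicate 2 and 1608 with only p4 and p5 in the fit.

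Endoderm genes took another course in HES2 and MEL1: from p4 to p5 they rose, in 16 of 22 cases in HES2 and 17 of 23 in MEL1, with 2 and 3 falls (adjusted over the list alone, rises 17 and 18, falls 3 and 3). For this list camera returned adjusted p = 1.44e-05 and 0.017; adjusted p = 0.107 and 0.616 with an estimated correlation. In H9 0 of 20 rose and 7 fell (the same adjusted over the list alone; camera adjusted p = 0.0144; adjusted p = 0.537 with an estimated correlation). The genes named in this paragraph, except TTR, APOB and KRT19, were chosen after their values were seen. AFP, the fetal plasma protein alpha-fetoprotein, rose from 11.03 ± 0.58 to 12.75 ± 0.17 in HES2 (3.30-fold, adjusted p = 4.83e-05) and from 13.16 ± 0.64 to 15.19 ± 0.29 in MEL1 (4.07-fold, adjusted p = 1.95e-05), and stood at 9.38 ± 0.61 and 8.88 ± 0.47 in H9 (-0.49 log2, adjusted p = 0.263). TTR, the thyroid hormone carrier transthyretin, rose 5.0-fold in HES2 and 4.06-fold in MEL1, against -0.82 log2 in H9 (adjusted p = 0.324). The H9 value leaned on p4 replicate 1, at 9.22 against 6.65 and 7.37 on replicates 2 and 3. The apolipoprotein gene APOB rose 4.72-fold in HES2 and 2.72-fold in MEL1, and APOA4 16-fold and 9.77-fold. The endoderm factor SOX17 rose 8.79-fold in HES2, and GATA4 at least 5.04-fold in HES2 and 2.59-fold in MEL1. In HES2 both, with GATA6, FOXA1 and FOXA2, were called highest in p5, and in MEL1 none of them was. The keratin gene KRT19 rose 2.86-fold in HES2 and 1.59-fold in MEL1 and fell 1.77-fold in H9 (adjusted p = 0.00289). Surface and keratin epithelium genes rose with them, 12 of 15 in HES2 and 13 of 15 in MEL1 with 2 falls in each, the same adjusted over the list alone (camera adjusted p = 1.44e-05 and 0.00214; adjusted p = 0.0556 and 0.391 with an estimated correlation).

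**Figure D3:**
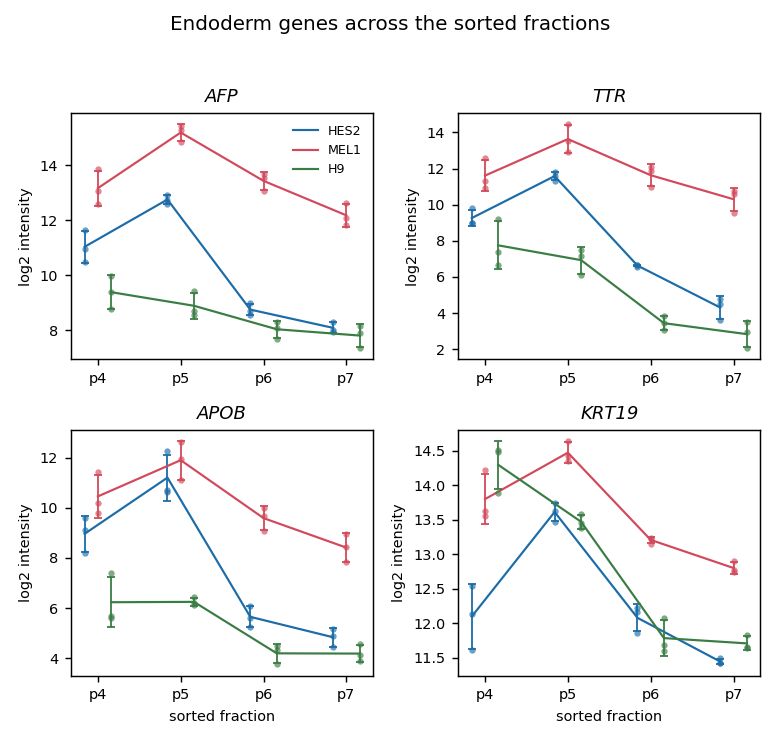
Log2 intensity of AFP, TTR, APOB and KRT19 in the sorted fractions p4 to p7; points are single arrays, lines join the means, bars are the SD (n = 3) and colour marks the line. In HES2 and MEL1 all 4 genes had their highest mean in p5 (AFP 12.75 in HES2 and 15.19 in MEL1), and in H9 AFP, TTR and KRT19 had theirs in p4.

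Between p5 and p6 the endoderm and stromal genes fell. The endoderm list had 20 falls of 22 in HES2, 20 of 23 in MEL1 and 16 of 20 in H9, with 0 rises (adjusted over the list alone, falls 20, 20 and 17; camera adjusted p = 3.35e-25, 1.87e-13 and 2.24e-19; adjusted p = 0.0121, 0.138 and 0.0548 with an estimated correlation). APOB fell 46.9-fold in HES2, 4.96-fold in MEL1 and KRT19 fell 2.89-fold, 2.40-fold and 3.22-fold in HES2, MEL1 and H9. Of the fibroblast and stroma list, 17, 20 and 23 genes fell with 0, 1 and 0 rises (adjusted over the list alone, falls 20, 22 and 24, rises 1, 1 and 0; camera adjusted p = 3.14e-17, 2.25e-14 and 3.09e-29; adjusted p = 0.0121, 0.107 and 0.0296 with an estimated correlation). The matrix proteoglycan gene LUM fell at least 44.8-fold in HES2, from 10.42 ± 0.77 to 4.62 ± 0.68, and PRRX1 at least 8.42-fold in H9. DPPA5, expressed in pluripotent cells, rose at least 2.47-fold in HES2 and at least 4.00-fold in MEL1. CD9 rose 1.85-fold in HES2 (adjusted p = 0.0071) and 1.90-fold in MEL1 (adjusted p = 0.000392), and its 1.36-fold difference in H9 had an adjusted p of 0.589. In all, 370 genes rose and 931 fell in HES2, 1592 and 1712 in MEL1, and 38 and 658 in H9. The HES2 total of 1301 was 866 without p5 replicate 2, 775 without p6 replicate 2, 2406 with array weights (48% of them higher in p6), 756 with only p5 and p6 in the fit and 678 with every array above the floor; the H9 total of 696 was 1069 without p4 replicate 2, 2819 with array weights (47.8% higher in p6), 1293 with only p5 and p6 in the fit and 350 with every array above the floor.

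Between p6 and p7 few genes differed. In HES2 the fibrinogen gene FGB fell at least 4.50-fold (adjusted p = 0.0331), APLNR 6.81-fold (adjusted p = 0.0331) and TTR at least 3.61-fold (adjusted p = 0.00391), among 9 genes that fell and 0 that rose. In MEL1 32 genes rose and 70 fell. There the interleukin subunit gene EBI3 rose at least 1.91-fold, and APLNR fell 4.98-fold (adjusted p = 0.0327; 3.10-fold without p7 replicate 1). In H9 limma called 0 genes, and 79 had an unadjusted p under 0.05. As a list, endoderm genes were lower in p7 than in p6 by camera, with adjusted p of 6.65e-19 in HES2, 2.25e-14 in MEL1 and 0.00021 in H9 (adjusted p = 0.0176, 0.127 and 0.362 with an estimated correlation); 5, 1 and 0 members fell over all genes and 10, 16 and 1 adjusted over the list alone. The HES2 count of 9 was 4 without p4 replicate 1 or p4 replicate 2 and 5 without p6 replicate 1, p6 replicate 2, p7 replicate 2 or p7 replicate 3; it was 0 with only p6 and p7 in the fit and 716 with array weights (43% higher in p7). The MEL1 count of 102 was 165 without p4 replicate 1, 59 without p6 replicate 2, 24 without p6 replicate 3, 30 without p7 replicate 1 and 51 without p7 replicate 3; it was 225 with only p6 and p7 in the fit, 303 with a replicate block, 269 with array weights and 54 with every array above the floor.

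Genes that changed from p4 to p7 had covered most of that change by p6. Placed on a scale with p4 at 0 and p7 at 1, the median gene in p5 stood at 0.644 in HES2 (quartiles 0.418 and 0.856), 0.645 in MEL1 (0.400 and 0.868) and 0.650 in H9 (0.479 and 0.798). In p6 the medians were 0.972, 0.942 and 0.987. No test was made on this scale; without H9 p4 replicate 2 the p5 median of H9 was 0.705.

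The average of p7 minus p4 over HES2, MEL1 and H9 was tested, which a gene changed in only some of the lines can also pass. Rises that passed in each line included CHST4, TRIML2 and LNCPRESS1, and such falls LHX2, TYRP1 and DLK1. In the average, 4571 genes were higher and 3768 lower in p7 of 11970 tested. Taken line by line, 1488 genes were higher in p7 in each of the 3 lines, where 260 would be shared if the lines were independent, and 1095 were lower in each, where 132 would be, of 10295 genes tested in all of them. HES2 and MEL1 shared 2433 genes higher and 2141 lower in p7, with 10 in opposite directions. H9 and MEL1 shared 2108 and 1578 with 362 in opposite directions, and H9 and HES2 1554 and 1131 with 259 opposite. Across genes, which are not independent replicates, the p7 minus p4 differences correlated at r = 0.923 (rho = 0.905) between MEL1 and HES2, 0.705 (rho = 0.642) between H9 and MEL1 and 0.662 (rho = 0.581) between H9 and HES2.

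The last comparison asked whether p7 minus p4 differed between lines, and line and medium cannot be separated in it because H9 alone was grown in mTeSR. Each line had also been normalised on its own by the authors, and its processing cannot be fully separated from line either. WNT3A, a Wnt ligand of the primitive streak and of the cortical hem, fell at least 125-fold in HES2 and at least 78.9-fold in MEL1, against -0.43 log2 in H9 (adjusted p = 0.474 there). NPY, the neuropeptide Y gene, fell 128-fold in H9 and lay below the floor in every fraction of HES2 and MEL1. HOXB8 fell at least 72.3-fold in H9, at least 6.49-fold in MEL1 and at least 2.79-fold in HES2. As lists, mesoderm (camera adjusted p = 1.26e-06 against HES2 and 8.66e-10 against MEL1), HOX clusters (1.25e-08 and 2.72e-08, and 0.0188 and 0.00174 over the 8 and 11 members tested in both lines) and fibroblast and stroma (1e-05 and 6.98e-07) fell further in H9; adjusted p = 0.173, 0.0719, 0.0619, 0.0619, 0.207 and 0.173 with an estimated correlation, in that order. The neural list fell less in H9 (camera adjusted p = 6.53e-09 and 1.58e-07; adjusted p = 0.046 for both with an estimated correlation, and 0.0731 and 0.112 over genes tested in both lines). The difference passed for 3662 genes between H9 and HES2 (1945 with the higher value in H9, 1717 with the lower), for 2825 between H9 and MEL1 (1532 and 1293) and for 320 between MEL1 and HES2 (150 higher in MEL1, 170 lower). The last count was 206 with all 36 arrays normalised together, of which 57.8% were higher in MEL1, 67 with every array above the floor and 647 with array weights; the count for H9 and MEL1 was 1753 with every array above the floor.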

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

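Every value in the next 3 paragraphs was singled out because the p7 minus p4 difference, or for endoderm genes p5 minus p4, differed between lines by a test of that difference. Line, medium and the separate normalisation of each line are confounded. H9 p4 replicate 2, in the last paragraph, was noticed from its position among the arrays. Tests chosen only after the result was seen were list differences with values floored, over genes tested in both lines and without H9 p4 replicate 2, and those of p5 as a mix of other fractions, of H9 with each p4 array left out, of the p5 and p7 shares and of an exchanged label. Values are differences of log2 differences, the first line minus the second; in brackets after a gene is the difference with every value below the floor raised to it, since all named genes but RSPO3 and MIR9-1HG had a mean below the floor in p4 or p7 of either line.

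Between H9 and HES2, 3662 genes differed. GPNMB, a glycoprotein of pigment cells and macrophages, differed by 7.15 (5.29), WNT3A by 6.88 (6.54) and the cytoskeletal adaptor SORBS2 by 6.22 (5.58), all having fallen in HES2. NPY, below the floor in every fraction of HES2 and MEL1, differed by -6.86 (-6.89), the steroid and bile acid glucuronidation gene UGT2B28 by -6.78 (-4.50) and HOXB7 by -6.51 (-4.65). Between H9 and MEL1, 2825 genes differed. The Wnt ligand WNT1 differed by 7.72 (5.03) and the globin genes HBG1 by 6.84 (5.59) and HBE1 by 6.40 (5.23), and NPY by -8.16 (-6.89), UGT2B28 by -7.22 (-4.79) and UGT2B7 by -6.96 (-5.84). Between MEL1 and HES2, 320 genes differed. NANOG differed by 5.76 (5.52), with its probe below the floor on all 12 arrays of HES2, the microRNA host gene MIR9-1HG by 4.25 (3.83) and RSPO3 by 4.03 (4.03). The pregnancy glycoprotein gene PSG7 differed by -4.42 (-3.21), the homeodomain-only gene HOPX by -4.22 (-2.46) and ODAM, an enamel-associated protein gene, by -4.21 (-2.13). In splits of the 6 replicates of each pair the highest other count was 27 against the real 3662, 9 against 2825 and 0 against 320, and the 10 splits are too few for a share under 0.05 (1 as large in each).

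Lists differed between H9 and the other lines in mean p7 minus p4. Against HES2 and MEL1 in that order, the neural list differed by 1.91 and 1.61 and the cell cycle list by 0.45 and 0.42. Those lower in H9 were pluripotency (-0.74 and -0.97), NODAL and TGF-beta signalling (-1.79 and -1.95), primitive streak and mesoderm (-2.19 and -2.48), trophoblast (-1.60 and -1.58), fibroblast and stroma (-1.37 and -1.33), surface and keratin epithelium (-0.85 and -0.64), mesenchymal transition (-1.42 and -1.24) and HOX clusters (-3.17 and -2.53). Camera adjusted p was 0.0106 and 0.000925 for pluripotency, 0.00031 and 1.26e-06 for NODAL signalling, 0.02 and 0.0072 for trophoblast, 0.00145 and 0.00523 for surface and keratin, 0.00772 and 0.00044 for mesenchymal transition and 0.000897 for cell cycle against both; the others are in the report. With an estimated correlation, adjusted p was 0.046 for the neural list against both lines and for NODAL signalling against MEL1, and above the threshold for the other calls: 0.118 for NODAL signalling against HES2, 0.512 and 0.401 for pluripotency, 0.173 and 0.0719 for mesoderm, 0.232 and 0.178 for trophoblast, 0.207 and 0.173 for fibroblast, 0.132 and 0.178 for surface and keratin, 0.207 and 0.132 for mesenchymal transition, 0.0619 for HOX against both and 0.207 for cell cycle against both. Without H9 p4 replicate 2 the pluripotency difference was -0.37 against HES2 (camera adjusted p = 0.221) and -0.60 against MEL1 (adjusted p = 0.0383), and the other calls named here stayed past the threshold, while BMP signalling (-1.08 against HES2) came past it (adjusted p = 0.0164). With an estimated correlation and without that array, adjusted p was under the threshold for cell cycle (0.0143 against both), HOX (0.0315 and 0.0331), neural (0.0315 and 0.0464), mesoderm against MEL1 (0.0464) and NODAL signalling against MEL1 (0.0315), so which lists passed with an estimated correlation depended on 1 array. Many members lay below the floor: of 18 HOX genes in the joint fit, 8 were tested in HES2 and 11 in MEL1. With values floored the HOX difference was -2.42 and -2.13 (camera adjusted p = 3.06e-10 and 1.43e-11; 0.0881 and 0.0638 with an estimated correlation), and over genes tested in both lines -2.25 and -1.93 (0.0188 and 0.00174; 0.391 and 0.292). By camera, trophoblast was no longer past the threshold with values floored (adjusted p = 0.0982 and 0.119), and the other calls named here held in both settings. With an estimated correlation, NODAL signalling against MEL1 was no longer past it in either (0.0547 and 0.0731), neural only over genes tested in both lines (0.0731 and 0.112), and mesoderm against MEL1 came past it with values floored (0.0329).

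Of the endoderm list, 13 of 22 genes in HES2, 7 of 23 in MEL1 and 0 in H9 were highest in p5; in mean p5 minus p4 the list differed by -1.79 between H9 and HES2 and by -1.38 between H9 and MEL1 (camera adjusted p = 3.68e-07 and 7.08e-07; adjusted p = 0.107 and 0.118 with an estimated correlation). Whether the wider spread of H9 p4 is the reason stays open. With any 1 of the H9 p4 arrays left out, limma found 0 endoderm genes highest in p5 of H9. An unadjusted p under 0.05 by limma was reached by 2, 0 and 0 of them without replicates 1, 2 and 3. In those fits 0 genes of any kind were highest in p5 and p4 had fewer arrays, so the count could hardly have risen. In H9 p4, TTR stood at 9.22 on replicate 1, against 6.65 and 7.37 on replicates 2 and 3. A mix of p4 with p6 or p7 cells cannot exceed its parts, which argues against it as the whole reason: over 1 log2 above every other fraction stood at least 148 genes in HES2 whichever p5 array was left out, and in MEL1 92, with 28 without p5 replicate 1, 26 without replicate 2 and 155 without replicate 3. Dependence on a single p5 array is argued against in HES2, with at least 160 peaks whichever was left out and 209 with all arrays. How many of the 209 were among them was not counted. Such dependence stays open in MEL1, where the count of 169 peaks fell to 46 without p5 replicate 1 or replicate 2. Endoderm-like cells with intermediate staining in p5, where AFP reached 12.75 in HES2 and 15.19 in MEL1, or an effect of line or medium, may account for the pattern; neither was tested.

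H9 p4 replicate 2 lay between the other p4 arrays and p5: on the first principal component of H9 it stood at -51.9 against -91.1 and -92.4. Much poorer RNA or a much poorer array is argued against. Over 889 genes with no change between fractions, replicate 2 differed from the other p4 arrays by 0.850 times the difference between those arrays. These genes were picked with the mean of those arrays near p5 and p7, which by itself lowers the ratio, so a slightly noisier array is not excluded. An exchanged label is argued against, as 0 arrays of p5, p6 or p7 lay closer to the other p4 arrays than to their own fraction. Cells of other fractions stay open: the mixed share was 0.50 from 827 genes higher in p7 and 0.44 from 747 lower ones, and the interval of their difference of 0.06 (95% bootstrap interval -0.08 to 0.18) passes the margin of 0.15 set for it. The make-up of that share differed, with 0.44 of p5 and 0.06 of p7 from the higher genes and 0.06 and 0.38 from the lower ones (differences 0.38, -0.02 to 0.571, and -0.32, -0.471 to -0.0295); the last interval leaves out 0, but over genes that are not independent, and 1 mix for both sets left median absolute residuals of 0.241 and 0.279 log2, against 0.234 and 0.259 with each set's own mix and 0.874 and 0.529 with none, so a mix and cells of an intermediate state cannot be told apart.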

How the results depend on the processing

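The offset, the floored values, the filters at the 60th and 80th percentile, list differences between lines without H9 p4 replicate 2, with values floored and over genes tested in both lines, and the block for neighbouring steps of lists were tests chosen only after the results were seen. Settings fixed in advance that could not be run were other background corrections, which need the scanner tables; the authors' table as an alternative, since it was used throughout; median scaling, since the values were already quantile normalised; and a chip block, since no label gives the chip. Over other settings of normalisation, filter, probe choice, block, weights, offset, floor and fractions in the fit, and with each array left out, list shifts between p7 and p4 had the same direction and side of the threshold by camera 1677 times, were no longer past it 23 times, newly past it 5 times and reversed 15 times, never for a list that had passed; an estimated correlation lost 28 of 47 calls. The list test fry, also run, asks whether a list moved and not whether it moved more than other genes, so its calls are of another kind. For named genes 10223 comparisons were the same, 121 no longer past and 1 reversed. With every array above the floor, fewer genes were tested and the counts were 678 for p6 against p5 in HES2, 350 in H9, 5 for p7 against p6 in HES2, 54 in MEL1, 1753 for the difference between H9 and MEL1 and 67 between MEL1 and HES2; the mean list shift turned to -0.32 for NODAL and TGF-beta signalling in HES2, 0.025 for glycolysis and hypoxia in HES2, -0.18 for surface and keratin epithelium in MEL1 and 0.10 for immediate early and stress in MEL1, none of which had passed camera. So did, with the filter at the 80th percentile, glycolysis in HES2 (0.025), immediate early and stress in MEL1 (0.11) and germ line in H9 (-0.0363), and without H9 p4 replicate 2 the differences between H9 and MEL1 for p53 targets (0.0480) and ribosomal proteins (0.0171). With values floored, differences that turned were those between H9 and HES2 for WNT signalling (0.0077), endoderm (0.0377) and endothelial and blood (0.0817) and between H9 and MEL1 for p53 targets (0.0268); over genes tested in both lines, those between H9 and HES2 for WNT signalling (0.0270) and glycolysis (0.0514) and between H9 and MEL1 for imprinted growth genes (0.0038), p53 targets (0.0629) and endothelial and blood (-1.59), which came past the threshold. None of these had a call before. With 1 array left out, lists with no call that took either sign were glycolysis (-0.0927 to 0.0376 in HES2, -0.0146 to 0.189 in MEL1, -0.101 to 0.0681 in H9), p53 targets (-0.0121 to 0.236 in MEL1, -0.0213 to 0.147 in H9) and immediate early and stress in MEL1 (-0.164 to 0.0619). With a replicate block, of the named genes PYDC1 alone, between p6 and p5 in H9, was no longer past the threshold, and the only counts that moved by over 1.5 times were 19 for p7 against p6 in HES2, 303 in MEL1, 490 between MEL1 and HES2 and 374 for genes highest in p5 of MEL1; list calls by camera were 6, 13 and 7 for p7 against p6 in HES2, MEL1 and H9 (7, 9 and 5 without the block), 17 and 19 for p6 against p5 in MEL1 and H9 (16 and 18) and 15 for p5 against p4 in H9 (13). With array weights, counts were 2406 for p6 against p5 in HES2, 2819 in H9, 716 for p7 against p6 in HES2, 269 in MEL1 and 647 between MEL1 and HES2; the cause was not tested. The count between MEL1 and HES2 was 206 with all arrays normalised together and 196 with the filter at the 80th percentile; the cause was not tested. With only the fractions compared in the fit, which leaves fewer arrays to estimate the spread, counts were 756 for p6 against p5 in HES2, 1293 in H9, 0 for p7 against p6 in HES2 by limma (9 with all fractions), 225 in MEL1 and 1608 for p5 against p4 in H9. Requiring a log2 difference over 1 left 2936 genes in HES2, 2832 in MEL1 and 2463 in H9 between p7 and p4, and an estimated correlation left 19 list calls. With the mean of its probes, MEST in MEL1 turned to -1.35 log2, as its second probe has the opposite sign. Leaving out 1 array at a time gave 775 to 1545 genes for p6 against p5 in HES2, 4 to 10 for p7 against p6 in HES2, 24 to 165 in MEL1, 1990 to 4536 for p5 against p4 in H9, 485 to 1069 for p6 against p5 in H9 and a p5 position of 0.628 to 0.705 in H9. Replicate residuals correlated over 0.1 between fractions in 8 of 18 pairs of equal number in HES2 (lowest -0.12), 17 in MEL1 (lowest 0.0986) and 14 in H9 (lowest -0.093). For p7 against p4 no line had over 0.1 in every pair, nor did any step in HES2. The correlation was the highest with the own number in 10 cases in HES2, 18 in MEL1 and 14 in H9. The account of the processing says for which comparisons the numbers were taken to pair. Dim signal limits the folds of genes whose mean in the lower fraction lay below the floor, which are given as lower bounds.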

Other observations

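Tests chosen only after the result was seen were the counts of genes highest in p5, the LIN28A tests and the mixed-fraction test. In HES2 209 genes were higher in p5 than in each other fraction, in MEL1 169 and in H9 0 by limma, where 30 had an unadjusted p under 0.05 (1 passed with the mean of a gene's probes); 57 were shared by HES2 and MEL1, where 3.31 would be if the lines were independent. Endoderm genes made up 13 of 22 tested list members in HES2 (0.419 would be there by chance; one-sided Fisher's exact test, adjusted p = 9.51e-16) and 7 of 23 in MEL1 (0.343; adjusted p = 1.09e-06). In HES2 surface and keratin epithelium (5 of 15, adjusted p = 0.000153), BMP signalling (4 of 14, 0.00165), mesoderm (4 of 15, 0.00185) and smooth muscle (3 of 17, 0.0316) also passed this exact test. In MEL1 trophoblast (3 of 7, adjusted p = 0.00165), BMP signalling (3 of 15, 0.0139) and smooth muscle (3 of 16, 0.0148) did. The exact test treats genes as independent, which list members measured on the same arrays are not. The estimated correlation of the endoderm list was 0.111 in HES2 and 0.494 in MEL1, so the p-values of this test are likely too small. The HES2 count was 86 with every array above the floor. The MEL1 count was 374 with a replicate block and 272 with array weights; left-out arrays moved it to 365, 56 and 90 (p4 replicates 1, 2 and 3), 46, 46 and 291 (p5 replicates 1, 2 and 3) and 111 and 101 (p6 replicates 2 and 3).

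LIN28A, an RNA-binding protein gene of pluripotent cells chosen after its values were seen, kept more of its p7 level in p4 than most pluripotency genes: 48.0% in HES2, 60.3% in MEL1 and 62.0% in H9, ranks 2 of 22, 4 of 24 and 1 of 23 among list members higher in p7. SALL4, another factor of that list, kept 60.9% in HES2 and 60.4% in MEL1. Carry-over of p7 cells into p4 would set a like share for all of these genes. It therefore cannot be the whole reason for a LIN28A share at least 3.98 times that of the lowest member above the floor in p4. LIN28A was picked for its high share, so this value only says that the shares were unlike. Carry-over of p5 cells could give unlike shares, since in p5 of MEL1 LIN28A stood near its p7 level and NANOG below it. That was not tested. Compression of bright signals could contribute and stays open: in HES2 only 2 genes as bright as LIN28A fell further in p4, against 10 in MEL1 and 11 in H9, although POU5F1, brighter in p7 of each line, fell further in all of them. The HES2 count rests on a narrow cut. L1TD1 and DPPA4, at 13.89 in p7 there against 13.92 for LIN28A (arrays from 13.81 to 14.09), kept 11.2% and 18.9%. A biological persistence of LIN28A in p4 cells was not tested.

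Other splits of the samples were counted for each comparison within a line, where 3 arrays against 3 make 10 splits, too few for a share under 0.05. The real counts between p7 and p4 were 5053, 7585 and 5401 in HES2, MEL1 and H9, against a highest other split of 0. For p5 against p4 they were 3567, 6439 and 3164 (highest other 0, 0 and 1), for p6 against p5 1301, 3304 and 696 (0 in each) and for p7 against p6 9, 102 and 0 (0 in each, so that all 10 splits equalled the real one in H9; 79 genes had an unadjusted p under 0.05 by limma there). For the average over lines, chance is argued against: 1 of 100 splits, drawn within each line, gave as many genes, the real one with 8339. The highest other gave 6357, so a large count by itself does not show a change common to the lines.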
